A study of Mus musculus with 30 samples.

How the data were processed

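Total RNA from mouse lung tumours was extracted with a column kit and made into libraries with the TruSeq RNA v2 kit, per the labels' protocols. The submitters' processing notes name TopHat 1.3.3, HTSeq and DESeq 1.14.0 and the mouse genome build mm9, with no role or order given. The authors deposited a single table of normalized values for the whole series, with 23284 gene rows and 30 columns. Samples were assigned to untreated, NAC and vitamin E from the treatment label, and to animals from the animal number label. Columns were to be assigned to samples only where the column name matched the labels of a single sample. No column met this rule, so all 30 columns of values were looked at only to see what kind of values they held. They were left out of all analysis, and no statistical test was run. The tests, gene lists and alternative settings chosen before the data were examined were not run for the same reason. The quantities reported were counts of samples, animals, gene rows and columns. The different letters and digits in the column names were counted too. So were the column names and index sequences that matched a label or a title.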

Results

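The series profiled gene expression by RNA sequencing in lung tumours that K-RAS, a small GTPase that drives growth signalling, had induced in mice. The labels place 30 tumour libraries in 3 groups of 10 each. One group of mice was left untreated, one received NAC and one received vitamin E. Each group held 5 animals, and each animal gave 2 tumours, so that the animal is the unit of replication and the study has 15 of them. The title of the series names antioxidants and the progression of lung cancer. The groups would allow each treated group to be compared with the untreated one and with the other, but the labels name no comparison.

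The comparisons between these groups were not made here, and no expression value, fold change or depth of a library is reported. The table of normalized values that covers the series holds 23284 gene rows in 30 columns. The column names combine a letter, of which 3 occur, a digit, of which 5 occur, and a further digit, of which 2 occur, with an index sequence. None of the 30 names matched the title, description, source or characteristics of a sample, and 0 of the index sequences stood in the labels. The name structure has the shape of 3 groups of 5 animals with 2 tumours each, but no source used here states which letter stands for untreated, NAC or vitamin E. The order of the columns was not accepted as evidence of a treatment, and no source beyond the labels, the series text and the table itself was used to look for a key to the letters. The direction of any change under NAC or vitamin E, including in p53 targets, NRF2 targets and the proliferation genes for which lists had been fixed before the data were examined, was therefore not analysed.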

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

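No paired analysis was possible because no column of values was assignable to a sample, and the labels give each of the 15 animals a single treatment, so that the shared letters in the titles are not stated to pair animals across groups. None of the processing alternatives listed before the data were examined was run, since no column was assigned. A looser matching of column names, chosen after the names were seen, asked only that the first 2 characters of a name stand in a title. It found titles for 12 of the 30 columns, each time 3 titles at once, one from each treatment. Each combination of letter and digit in the titles occurs once in every treatment, so this rule was bound to give no single sample and says nothing about how firmly the stricter rule holds.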
